A study of Mus musculus with 2 samples.

How the data were processed

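Total RNA of embryonic mouse lung was prepared with a column kit, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. Per the series' design text, RNA of 3 samples was pooled in equal amounts within each group before hybridisation, which gave 1 wild type and 1 Etv4 and Etv5 knockout array at E13.5. The labels give neither the deleted parts of the genes nor the sex of the embryos. The deposited table holds 1 value per probe set and array. The authors' deposited values were taken as log2 expression values from their range, and neither the log base, the summary method nor the normalization is given in the sources used here. The medians of both arrays were close (7.60 and 7.58), and the correlation across probe sets was 0.996, where probe sets are not independent replicates. Exactly equal values on both arrays were found for 10043 of 35557 probe sets (28.2%).

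Probe sets were named from the platform annotation: 21789 had 1 gene symbol, 1621 several and 12147 none in that table. Of the 21789, 21698 were found in a RefSeq gene table of the assembly GRCm38.p6, which served only for symbols, chromosomes and gene order, and 0 were renamed. Each gene was represented by the probe set with the highest mean log2 value among those with 1 symbol, which gave 19938 genes. A gene counted as measured when the brighter of its 2 values was at or above the median of its array, which left 11045 genes. Values were otherwise used as deposited, with no floor and no offset. For 618 genes with 2 probe sets, the median gap between their differences was 0.04 and the 90th percentile 0.18.

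With 1 array per group no test across samples was run and no p-value or SD was computed. Genes were counted when they differed by at least 2-fold. For each of 32 gene lists, the median log2 difference of measured genes was placed among 10000 random lists of the same size, drawn from 20 bins of mean level. Lists needed at least 3 measured genes. Of 554 distinct list genes 523 were matched. The lists, thresholds and the rule for named genes were fixed before the data were examined. The rule takes Etv4 and Etv5, up to 15 measured genes per direction that differ at least 2-fold, members of each list that do so (at most 4) or otherwise the 2 with the largest size, any member of the FGF, Hedgehog, distal tip and ureteric bud lists, and sex-linked genes.

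The steps were tested on simulated data built on the 11045 measured genes. Of 200 simulated changes, 0.5% of those of log2 0.5 and 100% of those of log2 1.5 and 2.0 were counted as 2-fold. Of 200 unshifted lists of 6, 15 and 25 genes, 6.0%, 3.5% and 2.0% lay outside the central range. An upward shift of 0.1 of every member was recovered in 93.0%, 100% and 100%, and downward shifts were not simulated. These lists were random genes with shuffled differences, so the shares check the steps only. They do not describe lists of genes that vary together. Alternatives were 3 other scalings (equal medians, quantile, loess with a span of 0.3), the mean over a gene's probe sets, no filter and a filter at the 75th percentile, a floor at the 25th percentile, thresholds of 1.5-fold and 3-fold, and random lists not matched on level. Leaving out X and Y genes, the mean of a list, and members on 1 list only were added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.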

Results

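Gene expression was measured in lungs of mouse embryos at E13.5, an embryonic stage at which the airway tree is still branching. The study set wild type lungs against lungs labelled as knockout for Etv4 and Etv5, a pair of ETS transcription factors expressed in the distal lung epithelium and induced by fibroblast growth factor (FGF) signalling. RNA of 3 samples per group was pooled, and each pool was read on 1 Affymetrix array, so there were 2 arrays and no replicates. No test across samples was therefore possible, and every difference below compares these 2 pools. The deposited values ranged from 2.72 to 14.4 on the wild type array and from 2.69 to 14.4 on the knockout array, with medians of 7.60 and 7.58 over 35557 probe sets. They were read as log2 values from this range, since the scale was not stated. Precision was limited by the number of arrays. Differences are given as knockout minus wild type on the log2 scale. A list of genes was said to stand apart when the median difference of its measured genes lay outside the central 95% of those of 10000 random lists of the same size and similar expression level. That percentile describes these 2 arrays only.

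The targeted genes had lower values in the knockout pool. Etv4 was read by 1 probe set, at 7.59 in wild type and 6.96 in knockout, a difference of -0.63 (1.55-fold). Both values lay under the array medians that served as the limit for measured genes, so Etv4 did not count as measured. Etv5 was read by 2 probe sets, which stood at 11.51 and 11.41 in wild type and at 11.28 and 11.17 in knockout, differences of -0.23 and -0.24. One label abbreviates the knockout as CKO and others call it a knockout, and neither a Cre line nor the deleted part of either gene was given in the sources used here. Whether the deletion covered all lung cells is therefore unknown, and a probe set outside the deleted part checks nothing. The related factor Etv1 differed by 0.03 and -0.06 on its 2 probe sets. The pools also differed in sex-linked genes. Xist, the RNA that silences 1 X chromosome in female cells, was at 12.34 in wild type and 5.74 in knockout, a difference of -6.60. The Y-linked genes Uty, Eif2s3y and Kdm5d were higher in knockout by 0.64, 0.53 and 0.53. This difference between the pools accompanies every gene group described here.

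Across the genome, few genes differed by 2-fold or more, and surfactant genes were among them in both directions. Sftpb, which encodes surfactant protein B, had the largest positive difference of the 11045 measured genes, 1.91 (from 9.12 to 11.04, 3.77-fold). Lamp3, a lysosomal membrane protein of the lamellar bodies that store surfactant, was higher by 1.42 (from 6.71 to 8.13, 2.67-fold). Sftpc, which encodes surfactant protein C and marks distal epithelium at this stage, was lower, with a difference of -1.12 (from 10.86 to 9.74, 2.18-fold). In all, 6 measured genes were at least 2-fold higher and 4 at least 2-fold lower in the knockout pool. The other higher genes were the dipeptidase gene Dpep2 (1.90), Cpxm2 (1.63), Anxa1, which encodes annexin A1 (1.39), and Edil3 (1.21). The other lower genes besides Xist were Cym, which encodes the milk-clotting protease chymosin (-1.78), and Cubn, which encodes the endocytic receptor cubilin (-1.36). Dpep2, Cpxm2, Lamp3 and Anxa1 lay below the array median in wild type, and Cubn and Xist lay below it in knockout, so the sizes of these 6 differences rest on a dim value. The 2 probe sets of Dpep2 gave 1.90 and 0.70. Of the 11045 measured genes 2836 were higher and 5193 lower, so lower genes outnumbered higher ones across these arrays, with a median difference of 0. The central 95% of measured genes lay between -0.22 and 0.20, and 3016 measured genes (27.3%) had exactly equal values on both arrays, for which no reason was given in the sources used here.

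**Figure D1:**
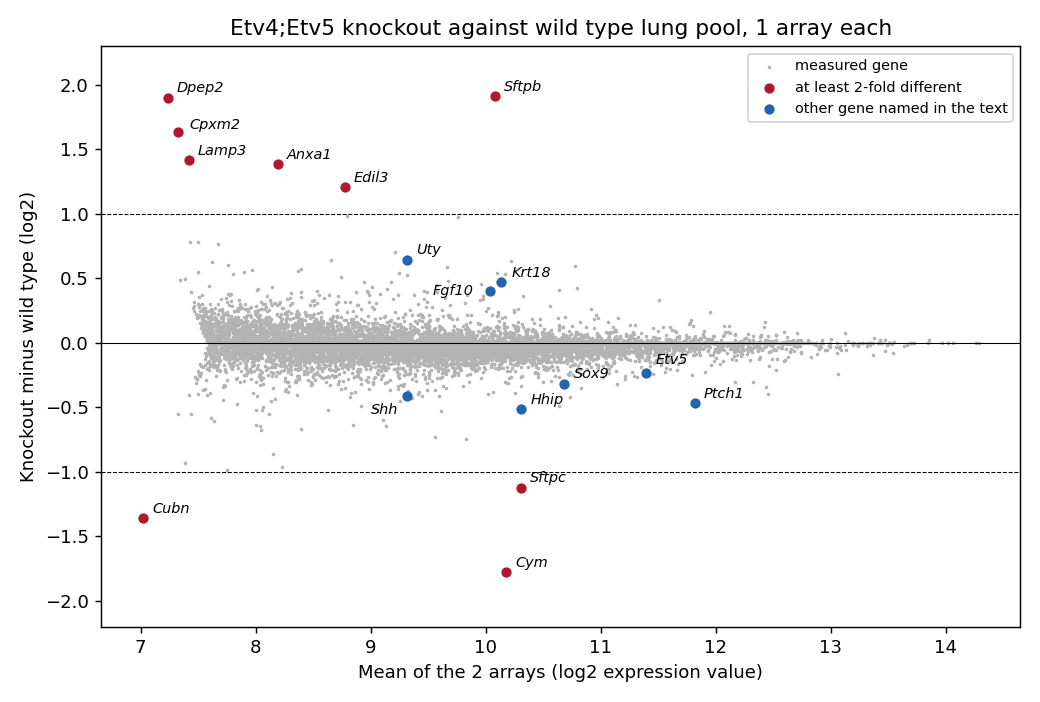
Difference between the pools (knockout minus wild type, log2, vertical axis) against the mean log2 value of the 2 arrays (horizontal axis) for each measured gene, with dashed lines at 2-fold. Sftpb (1.91) and Sftpc (-1.12) lie on opposite sides at similar mean levels; Xist (-6.60) falls outside the plotted range and is not drawn.

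The study asked how loss of these Etv factors affects the developing lung, and signalling and cell type genes were compared as groups. Hedgehog pathway genes, through which the epithelium signals to the mesenchyme, were lower in the knockout pool: 11 of 14 measured members were lower and 1 was higher. Shh, the ligand made by the epithelium, differed by -0.41 (from 9.52 to 9.11). Its receptor and target Ptch1 differed by -0.47, the target Hhip by -0.52, the mesenchymal factors Foxf1 and Foxf2 by -0.40 and -0.23, and the target Gli1 by -0.14, while the co-receptor gene Boc was higher by 0.13. The list's median was -0.08, at the 0.15th percentile. Several of these genes are expressed in mesenchyme, and the list of mesenchyme genes, which shares Foxf1, had a similar median of -0.07. The means of these lists were further apart, at -0.16 for Hedgehog and -0.08 for mesenchyme. Fgf10, the mesenchymal ligand that drives bud outgrowth and is known to be restrained by Shh, was higher by 0.40 (from 9.84 to 10.24).

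FGF ligands and receptors did not stand apart as a list (10 measured, median -0.011, 35.2nd percentile). Their mean was 0.0019, of the opposite sign to the median, and the median was above 0 under each of 3 other scalings. Fgf9 differed by -0.19 and Fgfr2, the epithelial receptor of Fgf10, by -0.11. Genes that respond to FGF and ERK signalling had a median of 0.00 at the 73.7th percentile, with 7 of 20 measured members higher and 9 lower. The feedback inhibitors Spry2 and Spry4 differed by -0.12 and -0.05 and Dusp6 by -0.0073, while Egr1 and Flrt3 were higher by 0.35 and 0.22. Of 4 genes that depend on Etv4 and Etv5 in the ureteric bud of the kidney, Myb differed by 0.12 and Met by -0.03, and Cxcr4 and Mmp14 were equal on both arrays (median 0.00, 62.5th percentile).

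Distal tip epithelium genes went both ways. Of 19 measured members 7 were higher and 11 lower, with 2 at least 2-fold higher (Sftpb, Lamp3) and 1 at least 2-fold lower (Sftpc). The list holds both targeted genes: Etv5 (-0.23) was among the lower members, and Etv4 did not count as measured. The progenitor factors Sox9, Id2 and Sox11 differed by -0.32, -0.31 and -0.18 and Muc1 by -0.27, whereas the protease gene Ctsh was higher by 0.43 and Bmp4 was equal on both arrays. The median was -0.016 at the 24.5th percentile and the mean 0.07. With a filter that kept only brighter genes the median was -0.11, at the 0.02nd percentile, and with the mean in place of the median the list lay at the 99.3rd percentile, so its direction depended on these choices.

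Epithelial genes in general were higher in the knockout pool. Of 26 measured genes shared by all lung epithelium, 20 were higher and 3 lower, with a median of 0.11 at the 100th percentile. The keratin genes Krt18 and Krt8 were higher by 0.47 and 0.33. All 6 measured proximal airway genes, of 19 listed, were higher, among them Aldh1a7 (0.41) and Klf5 (0.40), with a median of 0.15 at the 99.9th percentile. Neuroendocrine genes did not stand apart (3 measured, median 0.10, 95.4th percentile). Of 11 measured mesothelial genes 6 were higher, 2 lower and 3 equal on both arrays, with a median of 0.05 at the 99.9th percentile. Krt19, also a keratin of epithelia, was higher by 0.45, Bnc1 was higher by 0.20, and Fgf9 differed by -0.19. With the filter at the 75th percentile the median was 0.00 (78.8th percentile) and the list did not stand apart.

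Smooth muscle and mesenchyme genes were lower. Of 13 measured smooth muscle genes 11 were lower and 1 higher, with a median of -0.22 at the 0th percentile. Synpo2 differed by -0.49 and Myocd, the coactivator that drives smooth muscle genes, by -0.39. Of 24 measured mesenchyme genes 18 were lower and 4 higher (median -0.07, 0.01st percentile), although Fgf10 is one of the higher members. Erythroid genes, markers of blood in the tissue, were also lower in the knockout pool, with Slc4a1 at -0.26 and Hba-x at -0.25. Only 4 of 16 listed genes were measured, all of them lower (median -0.24, 0th percentile). The globin genes Hba-a1, Hbb-b1 and Hbb-b2 were not matched, so the list covers blood content only in part. Leukocyte genes were lower in 9 of 11 (median -0.09, 0.4th percentile), with Mrc1 at -0.17 and Csf1r at -0.15. Endothelial genes did not stand apart (21 measured, median -0.017, 25.8th percentile).

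**Figure D2:**
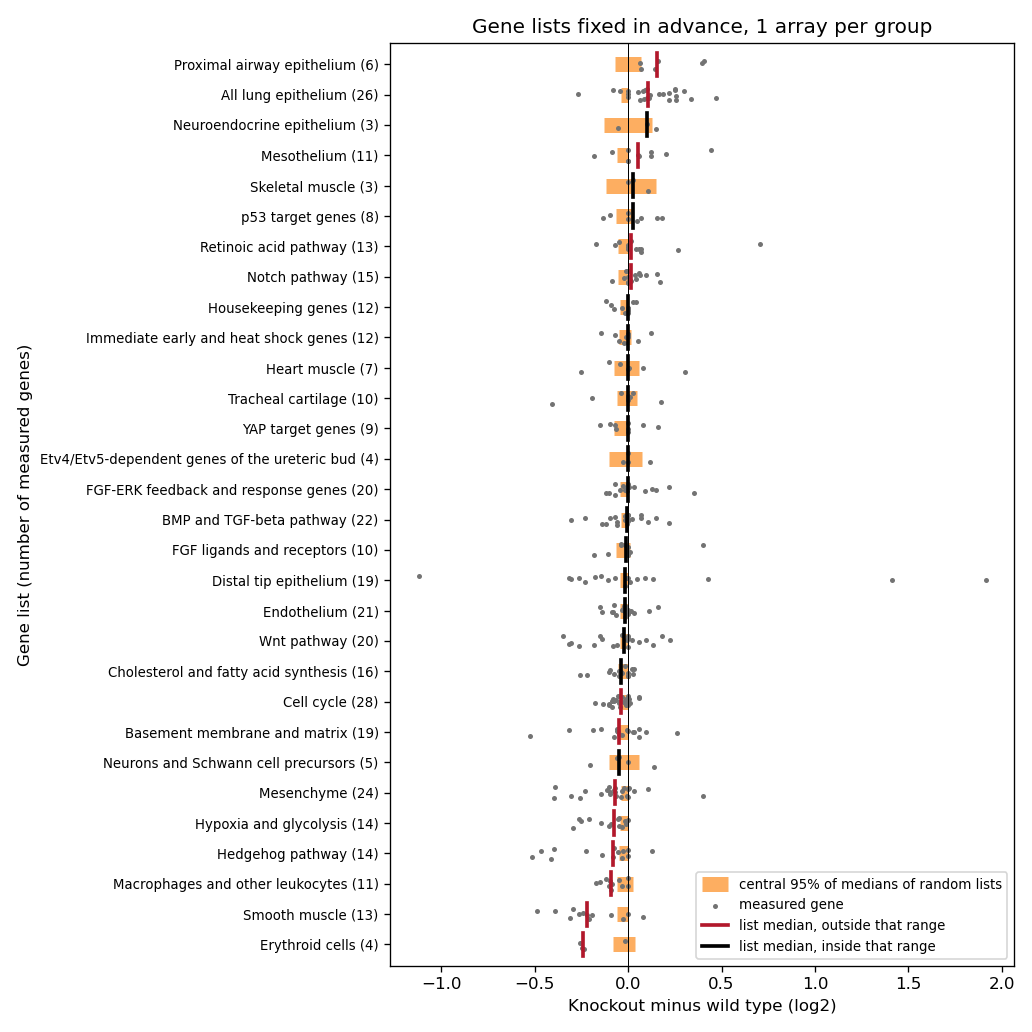
Difference between the pools (knockout minus wild type, log2, horizontal axis) for the gene lists (vertical axis, number of measured genes in brackets), with points for genes, bars for the central 95% of medians of random lists and lines for list medians. The medians of all lung epithelium (0.11) and smooth muscle (-0.22) lie on opposite sides of their random ranges.

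Among other signalling lists, Notch genes had a median of 0.014 at the 99.4th percentile, with Lfng at 0.17 and Jag1 at 0.15. Retinoic acid genes had a median of 0.016 at the 99.6th percentile, with the retinol transporter gene Stra6 at 0.70 and Aldh1a1 at 0.27. The random range ended at 0.00 for both lists, so a median barely above 0 was enough to stand apart. Both medians were smaller than the 0.017 by which equal medians moved the median of measured genes, so their signs carry no direction. That move applies to a list and its random lists alike, so it leaves the percentiles standing. Both lists still stood apart under the other scalings. Notch did not under the 75th percentile filter or the list mean, nor retinoic acid under that filter. The percentiles show only that both lists ranked above most random lists, by small amounts. Wnt pathway genes (median -0.020, 15.7th percentile), BMP and TGF-beta genes (-0.0044, 41.2nd) and YAP targets (0.00, 77.1st) did not stand apart, and Wnt5a and Wnt2b differed by -0.35 and -0.32. Hypoxia and glycolysis genes were lower in 13 of 14 (median -0.07, 0.09th percentile), with Bnip3 at -0.30 and Egln3 at -0.26. Cell cycle genes had a median of -0.037 at the 1.98th percentile, with Bub1 at -0.18 and Kif11 at -0.14. Basement membrane and matrix genes had a median of -0.05 at the 1.95th percentile, with Tnc at -0.53 and Nid1 at -0.31. The last 2 lists lay inside the random range under some alternative settings, as did Notch, retinoic acid and mesothelium.

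No other list stood apart. Percentiles were 53.7 for tracheal cartilage, 11.5 for neurons and Schwann cell precursors, 58.9 for heart muscle, 75.7 for skeletal muscle, 97.3 for p53 targets, 64.4 for immediate early and heat shock genes, 9.46 for cholesterol and fatty acid synthesis and 83.0 for housekeeping genes. Liver genes had 2 measured members and no percentile. Of 31 lists with a percentile 14 stood apart, where chance gives 1.55 if lists and genes are independent, which they are not. That count includes the sex-linked list (100th percentile), whose percentile carries no direction because Xist and the Y-linked genes oppose each other. It also includes the Notch and retinoic acid lists, whose medians lay barely above a random range that ended at 0.00.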

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

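The settings that left out X and Y genes, took the mean of a list, or kept members on 1 list only were chosen after the data were seen. With 1 array per group no array could be left out. The count of 6 higher genes was 2 with the filter at the 75th percentile, 19 at 1.5-fold and 3 at 3-fold, and the count of 4 lower genes was 18 at 1.5-fold and 2 at 3-fold; these follow from fewer genes or another threshold. Without X and Y genes the counts were 6 and 3. The distal tip median was -0.11 with the filter at the 75th percentile (0.02nd percentile). With the mean the list lay at the 99.3rd percentile, in the opposite direction. Sftpb (1.91) and Lamp3 (1.42) pull this mean up and Sftpc (-1.12) pulls it down, while 11 of 19 measured members were lower and 7 higher. A mean without these genes was not computed. The percentile of the sex-linked list was 0.11 with the mean, because Xist outweighs the Y-linked genes. Hedgehog medians lay between -0.08 and -0.06, smooth muscle between -0.22 and -0.20 and all lung epithelium between 0.10 and 0.13 over the planned settings, all outside their random ranges. Cell cycle genes no longer stood apart under quantile, loess, the probe set mean and the list mean, basement membrane under quantile and the list mean, Notch under the 75th percentile filter and the list mean, and retinoic acid and mesothelium under that filter. The p53 targets came to stand apart under loess, that filter and unmatched lists, and neuroendocrine genes under unmatched lists. Equal medians moved the median of measured genes by 0.017, so signs of list medians this close to 0 carry no direction. Dpep2 was 1.30 over its probe sets and Xist -6.19 with the floor. Dim signals limit most of the higher genes, of which 2 passed the stricter filter.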

Other observations

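Every test of an explanation, the added gene lists and the scan of gene families in this part were chosen after the values were seen. Just below the 2-fold threshold, and named after their values were seen, stood Phlda2 (0.98) and Tmem171 (0.98) among the higher genes and Cpn1 (-0.98) and Far2 (-0.97) among the lower. Genes of alveolar type 1 cells, which form the gas exchange surface, went both ways: Ager and Pdpn differed by -0.35 and -0.28, Aqp5 and Emp2 by 0.37 and 0.36, and the list's median was 0.00 (7 measured, 62.7th percentile). A list of surfactant and type 2 cell genes had a median of -0.016 (9 measured, 23.9th percentile). Of its 12 matched genes 5 were higher and 5 lower, with Sftpa1 at -0.30 beside Sftpc, and Ctsh at 0.43 beside Sftpb and Lamp3. Neutrophil genes could not be judged, since 0 of 13 passed the level filter; their median was -0.0017, and Ngp and Lcn2 differed by -1.02 and -0.96 at dim levels. Of 164 gene families with at least 8 measured members, 5 stood apart as higher and 7 as lower, against 8.2 by chance. Annexin genes were among the 5, with 5 of 8 higher and a median of 0.06 (99.9th percentile).

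Surfactant genes differed in opposite directions, Sftpb by 1.91 and Lamp3 by 1.42 against -1.12 for Sftpc. A difference in stage between the pools stays open: all 3 genes rise as the lung matures, but the value of -1.12 for Sftpc is part of the pattern itself and so does not test it. Of Sftpb and Sftpc, 0 lie on chromosome 11 (Etv4) or 16 (Etv5). For these 2 genes this argues against sequence differences linked to the targeted loci that act on genes of their own chromosome. Gene position cannot speak to effects that reach other chromosomes, and these were not tested. Lamp3 is on chromosome 16, 24 measured genes from Etv5, so linkage stays open for it. The 40 measured neighbours of Etv5, taken from both sides, had a median absolute difference of 0.015 (9.38th percentile, largest 1700025H01Rik at 0.25). They do not reach Lamp3 and so do not describe its surroundings. The neighbours of Etv4 had a median absolute difference of 0.034 (62.1st percentile, largest Coa3 at -0.40). An effect of genotype may be involved, and it cannot be separated here from variation between embryos or from the sex makeup of the pools.

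Epithelial genes were higher and smooth muscle genes lower, which a larger epithelial share in the knockout pool could give. For smooth muscle, the median of -0.22 lay at the 0.0th percentile of equal-sized draws from 45 mesenchyme and endothelium genes (-0.08 to 0.00). An equal lowering of smooth muscle, mesenchyme and endothelium genes would not give this gap, which argues against a larger share as the whole cause. That holds only if the share lowers these lists alike, and the medians of mesenchyme (-0.07) and endothelium (-0.017) themselves differed. Other lists outside the lung epithelium were not in the draws. The erythroid median was -0.24, near that of smooth muscle, and the leukocyte median -0.09, while the mesothelial median was 0.05. The list medians were known when the comparison was chosen, so it is not an independent test. For the epithelial genes a larger epithelial share stays open, because the endothelial median lay at the 25.75th percentile, between the limits set for either answer. That test used the endothelial list only. The mesenchyme, leukocyte and erythroid lists were lower (0.01st, 0.4th and 0th percentile) and the mesothelial list higher (99.9th), and these were not part of it. Less trachea in the knockout pool also stays open: proximal airway genes lay at the 67.96th percentile of draws from all lung epithelium, and tracheal cartilage genes had a median of 0.00 with 3 of 10 higher and 3 lower (53.7th percentile, Cnmd at -0.41 and Col2a1 at -0.19), which decides neither way. The limit for excluding it was first written as the 50th percentile, under which this value counted against the explanation, and was moved to the upper end of the central 95% of draws after the value was seen, because 6 genes above the middle of the draws were judged too weak to exclude it; the endothelial test was added, and the smooth muscle and epithelial parts separated, at the same time.

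Xist was lower and Y-linked genes higher in the knockout pool, which fewer female embryos in it could give. The 4 X-linked genes known to escape inactivation were then lower too: Kdm6a differed by -0.27, Eif2s3x by -0.21, Ddx3x by -0.19 and Kdm5c by -0.17, with their median at the 0.02nd percentile of random lists. One makeup that would give these values is 1 female among the 3 wild type samples and none in the knockout: the mean wild type to knockout ratio of the 3 Y-linked genes was 0.675 (0.640 to 0.695), against 0.667 for 2 of 3. Sry, a further measured Y-linked gene outside the fixed list, was higher by only 0.17. The makeup is a hypothesis, and whether sex contributes to the other gene groups cannot be told from 1 array per group.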
